A study of Mus musculus with 11 samples.

How the data were processed

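RNA was sequenced from pancreatic islets of mice that lack Zzef1 in beta cells, according to the labels, and of littermate controls. All mice received a high-fat diet for 4 weeks and were 16 weeks old. Islets were treated for 24 h with azoramide at 10 µM or with DMSO, the solvent, and each sample pooled islets of at least 3 mice. The 11 libraries fell into 4 groups: 3 control libraries with DMSO, 3 control libraries with azoramide, 2 libraries labelled knockout with DMSO and 3 labelled knockout with azoramide. Groups and replicate numbers were taken from the sample titles, which name the knockout as βZKO_Mip.

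The authors deposited raw read counts per gene for 32285 genes in 1 table with a column per library, unnormalized, and the unit was checked from the values. Alignment with STAR 2.7.2a and the mouse build mm10 are named in the submitters' processing notes, which also name DESeq2 with no role given. The counting tool, gene annotation and strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart from these counts. Sequencing used the DNBSEQ-T7 platform, per the labels. Library totals ran from 16832800 to 19501813 counts, with 17687 to 17999 genes detected per library, so counting error was small for all but weakly expressed genes. No pair of libraries within a group agreed within sampling noise, and all 11 were kept as separate samples. Total depth did not separate the groups.

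Coordinates, exonic length and GC content came from the GENCODE M21 annotation of GRCm38, the assembly called mm10. Of the gene identifiers, 32235 had an entry there and 32158 had a length and GC content. Coordinates are 1-based.

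Differential expression was computed from the counts in R 4.3.3 with edgeR 4.0.16, using its quasi-likelihood test with robust dispersion, TMM scaling and the filter for low counts by group, which left 15093 genes. All 11 libraries entered a single fit of 4 groups, so that the group of 2 shared the estimate of spread. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and fold changes are log2 values with their standard error (SE). Levels are CPM, counts scaled to library size, after TMM scaling, as mean ± SD. The comparisons were labelled knockout against control with DMSO and with azoramide, azoramide against DMSO in each genotype, and the interaction, that is the azoramide effect in libraries labelled knockout minus that in control islets. An average of both genotype comparisons was added after the data were seen. On simulated counts with 200 changed genes, the step for azoramide against DMSO in control islets, run on 14823 genes, recovered 46.3% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 93.9% of those changed 4-fold. For labelled knockout against control with DMSO, run on 14834 genes, the shares were 55.2%, 67.2% and 86.4%.

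Before the data were examined, 36 gene lists were fixed, of which 34 had at least 5 tested members; the lists of lymphocyte and adipocyte markers did not. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. The same test with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. Counts of list members past the threshold are over all genes tested. Marker lists and shares of counts per library were compared between treatments and between genotypes by 2-sided exact permutation tests, adjusted over 10 marker lists or 6 library measures. Each test ran over all 11 libraries without regard to the other factor. After the data were seen, medians of 10 lists were placed among 10000 random lists matched on exonic length, GC content and expression. Correlations of fold changes are across genes, which are not independent replicates, and were set beside 20 simulated sets of unchanged groups. The simulated values for genes with log2 CPM of at least 3 were added after the data were seen.

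Genes were named by a rule also fixed before the data were examined. It took Zzef1, 10 genes rising and 10 falling most among those past the threshold with mean log2 CPM of at least 1, an established symbol and no overlap between groups, up to 4 members per list with the smallest p, and Ins1, Ins2, Gcg, Sst, Ppy, Hspa5, Ddit3, Atf4, Xbp1 and Atp2a3 whatever their result. Where fewer than 5 genes passed, the 5 of smallest p with an established symbol, so no Gm number or Rik clone, were named as not past the threshold. Some genes that the rule gives are not reported here. For azoramide the rule gave 142 genes in control islets and 146 in libraries labelled knockout; the text discusses a subset of these, picked for the biology after their values were seen, so stability is given below for all genes of the rule as well.

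Alternatives fixed beforehand were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, only the groups compared, counts thinned to the smallest library, acinar markers as a covariate, the replicate number as a block, a 2-fold minimum, and each library left out in turn. Added after the data were seen were plain library totals, an offset per library for exonic length and GC content, the removal of ribosomal protein and mitochondrially encoded genes, and the joint removal of control DMSO library 2 and labelled knockout azoramide library 3, which stood apart on the principal components.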

Results

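Azoramide, a small molecule known as a modulator of the unfolded protein response, was applied to islets of mice on a high-fat diet, with and without a beta cell deletion of Zzef1, which encodes a large zinc-finger protein. RNA counts were obtained for 11 islet samples: 3 control samples with DMSO, 3 control samples with azoramide, 2 samples labelled knockout with DMSO and 3 labelled knockout with azoramide. Depth was 16832800 to 19501813 counts per library. The first principal component held 38.2% of the variance and separated azoramide from DMSO; the second held 11.8%, with control DMSO library 2 and labelled knockout azoramide library 3 at its opposite ends. Each sample held islets of at least 3 mice, and the labels do not say whether samples of a genotype share mice.

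The targeted gene was examined first. Zzef1 (chromosome 11, 72796226 to 72927120, plus strand, GRCm38; 55 exons in the transcript measured) was read in every library. With DMSO its level was 97.2 ± 12.2 CPM in control islets (SD, n = 3) and 81.5 ± 2.9 CPM in libraries labelled knockout (SD, n = 2). With azoramide it was 66.6 ± 2.0 CPM in control islets (SD, n = 3) and 72.8 ± 4.5 CPM in libraries labelled knockout (SD, n = 3). The difference between genotypes was -0.26 on the log2 scale with DMSO (SE 0.09, 95% interval -0.44 to -0.07, edgeR adjusted p = 0.999 over all genes) and 0.13 with azoramide (SE 0.08, adjusted p = 0.968). The libraries of the 2 labels did not overlap in either treatment, but those labelled knockout were lower with DMSO and higher with azoramide. Counts over the whole gene would not show the loss of a short exon if the rest of the transcript kept its level. Islets also hold other cells besides beta cells. These libraries are therefore called labelled knockout throughout, and every direction drawn from genotype rests on the label alone.

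**Figure D1:**
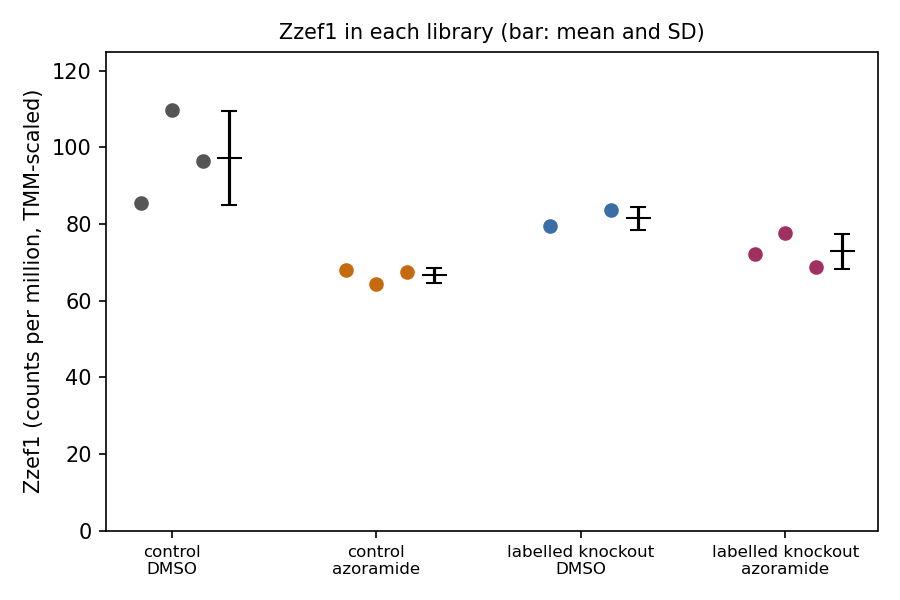
Zzef1 level in CPM after TMM scaling (vertical axis) in each library, by group (horizontal axis); points are libraries and bars give mean and SD. Control islets with DMSO averaged 97.2 CPM and libraries labelled knockout with DMSO 81.5 CPM.

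Which genes the loss of Zzef1 alters was asked first with DMSO. The hormone genes were at similar levels: Ins1, an insulin gene, was at 32781 ± 1500 CPM in control islets (SD, n = 3) and 31245 ± 455 CPM in libraries labelled knockout (SD, n = 2), and glucagon (Gcg) was at 14849 ± 833 and 14991 ± 1372 CPM. Hspa5, the ER chaperone BiP, differed by -0.14 (SE 0.14), Atf4 by -0.14 (SE 0.12), Ddit3, which encodes CHOP, by -0.18 (SE 0.18), and Atp2a3, the ER calcium pump SERCA3 encoded near Zzef1 on chromosome 11, by 0.15 (SE 0.09). None of the 15093 genes passed the threshold in the edgeR test, while 531 had an unadjusted p under 0.05; the DESeq2 test called 3. Without control DMSO library 2 the edgeR test called 1 gene, and without control DMSO library 3 it called 3. The smallest p was that of Gm15446 (adjusted p = 0.623), whose kind of symbol the naming rule leaves out. Among established symbols those of smallest p were Mt2 (-0.46, adjusted p = 0.660), Nr1d1 (0.56), Taf9 (-0.75), Fabp4 (-0.55) and Csf3 (-2.04), the last 4 at an adjusted p of 0.999. Mt2 was called by DESeq2 (-0.46, adjusted p = 0.00626) and by edgeR without the filter on low counts (-0.46, adjusted p = 0.0305).

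Of the 34 gene lists, 12 passed with the preset correlation with DMSO, 10 of them lower in libraries labelled knockout, although no member of any list passed alone. The list of glycolysis and hypoxia genes had a median of -0.51 (adjusted p = 3.4e-17), but its level in control DMSO library 1 was 6.39 mean log2 CPM against 5.37 to 5.73 in the other 10 libraries, and without that library the median was -0.13, still called (adjusted p = 1.1e-05). Lists of NF-kB genes (-0.37) and acinar markers (-0.79) were also lower. Without control DMSO library 2 the NF-kB median was -0.11 (adjusted p = 0.114) and the acinar median 0.37 (adjusted p = 0.242), and without labelled knockout DMSO library 2 or 1 the acinar median was -0.10 or -2.20. None of the 12 passed with an estimated correlation, where the smallest adjusted p = 0.636, or with fry.

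The same comparison with azoramide gave similarly few differences. Ins1 differed by -0.12 (SE 0.09), Ins2 by -0.28 (SE 0.13), Gcg by -0.10 (SE 0.07), Hspa5 by 0.02 (SE 0.13) and Atp2a3 by -0.06 (SE 0.09). No gene passed in edgeR, 754 had an unadjusted p under 0.05, and DESeq2 called 2. Without labelled knockout azoramide library 3 the edgeR test called 3 genes. With control DMSO library 2 left out as well it called 84, 49 higher and 35 lower in libraries labelled knockout. Control DMSO library 2 is in neither group compared here, so its removal acts through the shared fit, such as its estimate of spread. With all libraries, genes of smallest p included Cspp1 (0.29), Def8 (-0.32), Malat1 (0.34) and Nktr (0.25), all at an adjusted p of 0.826. Nktr (0.24, adjusted p = 0.0366) and Cttnbp2 (-2.88, adjusted p = 0.00333) were the DESeq2 calls. Cspp1, Def8, Malat1 and Nktr were all among the 84. Of the lists, 7 passed with the preset correlation, among them macrophage markers with a median of 0.41 (adjusted p = 1.6e-10) and ribosomal protein genes with a median of -0.11 (adjusted p = 1.7e-09); none did with an estimated correlation, where the smallest adjusted p = 0.833. The macrophage median was 0.24 without labelled knockout azoramide library 1 and 0.64 without control azoramide library 3. The ribosomal protein median was -0.07 with the length and GC offset and with plain library totals. Genotype effects with DMSO and with azoramide were uncorrelated across genes (r = -0.04), within the simulated range of -0.06 to 0.03.

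Expression differed widely between azoramide and DMSO libraries in both genotypes. The treatments also stood apart in a trend with transcript length, given below, whose source was not tested. In control islets 2908 genes rose and 2985 fell, 266 of the 5893 by at least 2-fold, and in libraries labelled knockout 3014 rose and 2992 fell, 469 of the 6006 by at least 2-fold. Both directions are relative to TMM scaling: with plain library totals the median of all genes shifted by -0.17 and -0.16, and the share of called genes that rose moved from 49.3% to 24.8% in control islets and from 50.2% to 29.1% in libraries labelled knockout. With an offset for exonic length and GC content 3490 and 3721 genes were called, of which 60.1% and 56.7% rose.

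Cyp1a1, a cytochrome P450 induced by the aryl hydrocarbon receptor, rose from 3.62 ± 0.82 to 40.3 ± 7.2 CPM (SD, n = 3 each; log2 fold change 3.47, SE 0.17, edgeR adjusted p = 4.3e-09), and by 2.86 in libraries labelled knockout (SE 0.19). The metallothioneins Mt1 and Mt2 rose by 1.40 (SE 0.07) and 1.47 (SE 0.08) in control islets. Neurotensin (Nts) rose by 1.77 and 2.57 in control islets and libraries labelled knockout. The early growth response gene Egr1 rose by 1.46 in control islets. In libraries labelled knockout its value was 1.13, and 0.88 without KO_DMSO 1. Without KO_Azoramide 2 or KO_Azoramide 3 it was 1.11 and 1.02 and missed the threshold (edgeR adjusted p = 0.0556 and 0.0537). The call was kept when KO_Azoramide 3 and control DMSO library 2 were left out together. Genes that fell included Ltbp2, a matrix protein gene (-2.16 and -2.49), Insrr, an insulin receptor relative (-1.74 and -2.10), and Tcp11 (-1.70 and -2.53). The cation channel gene Trpm2 fell by 1.79 in control islets; in libraries labelled knockout its log2 fold change of -1.67 became -1.44 (adjusted p = 0.0553) without labelled knockout DMSO library 2. Cttnbp2 had a value of 1.91 in control islets, where its spread was wide (24.1 ± 16.3 CPM with azoramide, SD, n = 3). It was at 1.73 or 1.72 (edgeR adjusted p = 0.0854 and 0.0864) without control DMSO library 1 or 3. Of 19 other settings, these 2 included, 5 ended the call, and values ranged from 1.2 to 2.4. In libraries labelled knockout the hepcidin gene Hamp had a value of 3.98, with adjusted p = 0.0874 (4.33) and 0.119 (3.69) without labelled knockout DMSO library 1 or 2.

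Islet hormone genes moved in different directions. Ins1 fell from 32781 ± 1500 to 23882 ± 1750 CPM in control islets (SD, n = 3 each; log2 fold change -0.46, SE 0.09, edgeR adjusted p = 5.3e-04) and by 0.50 on the log2 scale in libraries labelled knockout. Iapp, which encodes islet amyloid polypeptide, rose by 0.77 and 0.75, Gcg by 0.78 and 0.66, and peptide YY (Pyy) by 0.78 and 0.69. With the length and GC offset the Iapp values were 0.12 and 0.01 and no longer passed, nor did Gcg in libraries labelled knockout (0.21; 0.37 in control islets), while Ins1 was at -0.86 and -0.93. Ins2 was at 0.42 in control islets (SE 0.13, adjusted p = 0.0241) and 0.26 in libraries labelled knockout (SE 0.14, adjusted p = 0.192; 0.36 with adjusted p = 0.0327 and acinar markers as a covariate). The control call ended without control azoramide library 1 (0.34, adjusted p = 0.0778) or 3 (0.39, adjusted p = 0.0700) and without control DMSO library 1 (0.42, adjusted p = 0.0535), 2 (0.42, adjusted p = 0.0846) or 3 (0.42, adjusted p = 0.111), with plain library totals (0.25, adjusted p = 0.105) and with the length and GC offset (0.27, adjusted p = 0.242). Pancreatic polypeptide (Ppy) was at 0.51 (adjusted p = 0.0444) and 0.50 (adjusted p = 0.0750); its control call ended without control azoramide library 1, 2 or 3 (0.52, 0.50 and 0.54) or control DMSO library 3 (0.57), with plain library totals (0.34) and with the length and GC offset (0.24, adjusted p = 0.479). Ppy in libraries labelled knockout was called by DESeq2 (adjusted p = 0.0241), with only the groups compared (3.1e-04) and without both libraries that stood apart (4.8e-05), at 0.49 to 0.50. Somatostatin (Sst) was at 0.24 and 0.14, past the threshold in neither. Its control value was called in 4 other settings, at 0.22 to 0.30 (adjusted p = 0.00313 to 0.0405), and was -0.01 with the length and GC offset. Its value in libraries labelled knockout turned negative in 5 of 18 settings, to -0.09 at the lowest, and was called in none. Of 24 tested beta cell identity genes, 5 rose and 9 fell in control islets, and 5 rose and 10 fell in libraries labelled knockout, with no call for the list (adjusted p = 0.281 and 0.153). The length and GC offset gave a downward call for the list in both, at medians of -0.10 and -0.18 (adjusted p = 0.0317 and 0.0155). In control islets camera also called it downward without control DMSO library 2 (-0.24, adjusted p = 0.0343) and without both libraries that stood apart (-0.24, adjusted p = 0.0240). Fry called it downward in libraries labelled knockout (adjusted p = 0.0463). The beta cell transcription factor gene Nkx6-1 fell by 0.73 and 1.02, and Abcc8, the sulfonylurea receptor of the potassium channel, by 0.44 and 0.62, with -0.06 and -0.18 and no call under the length and GC offset. The urocortin 3 gene Ucn3 rose by 0.55 in control islets (0.28 with that offset). Of 29 granule and exocytosis genes 12 fell and 3 rose in control islets, and 13 fell and 4 rose in libraries labelled knockout, including chromogranin A (Chga, -0.49 and -0.72) and Ptprn2 (-0.47 and -0.51; -0.20 and -0.23 with the offset); the list was not called (adjusted p = 0.133 and 0.0832), except downward with plain library totals (adjusted p = 0.0395 and 0.0302) and with fry (0.00302 and 0.00139), and in libraries labelled knockout without the filter on low counts (0.0419). With the length and GC offset the control median was -0.02.

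Of 29 tested genes of ER folding and degradation, 14 rose and 4 fell in control islets (median 0.23, camera adjusted p = 0.00849) and 19 rose and 3 fell in libraries labelled knockout (median 0.38, adjusted p = 4.2e-04). Neither call held with an estimated correlation, with adjusted p = 0.754 and 0.614, and without control DMSO library 3 the control median was 0.16 (adjusted p = 0.0871). Without control DMSO library 2 it was 0.38. The medians were 0.12 and 0.26 with the length and GC offset and 0.07 and 0.23 with plain library totals, still called in each. Beside random lists matched on length, GC content and expression, the medians of 0.23 and 0.38 lay at percentiles 64.2 and 92.9. Counts adjusted over the list alone were 19 and 23. Hspa5 rose by 0.53 (SE 0.13) and 0.70 (SE 0.14), Pdia3, a protein disulfide isomerase, by 0.76 and 0.82, and Sec61b, a subunit of the ER translocon, by 0.66 and 0.81, while Sel1l, a component of the ER degradation machinery, fell by 0.48 (0.31 with the offset) and 0.57. Sec61g rose by 1.36 in control islets. Xbp1, a transcription factor of the unfolded protein response, was at 0.08 in control islets (SE 0.06, adjusted p = 0.345; 0.15 with adjusted p = 0.0489 without control DMSO library 2, and -0.09 with plain library totals) and 0.24 in libraries labelled knockout (SE 0.07, adjusted p = 0.0129; 0.21 with adjusted p = 0.134 without labelled knockout DMSO library 2, and 0.09 with adjusted p = 0.356 under plain library totals).

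Targets of the integrated stress response moved both ways, with no call for the list (adjusted p = 0.964 in control islets and 0.264 in libraries labelled knockout). Of 32 tested genes 7 rose and 5 fell in control islets, and 10 rose and 4 fell in libraries labelled knockout, where the list was called with the length and GC offset (median 0.31, adjusted p = 0.0310). Asns, asparagine synthetase, rose by 0.49 (0.33 with plain library totals) and 0.63; Sesn2 fell by 0.44 and 0.52 and the amino acid transporter gene Slc7a5 by 0.44 and 0.43, both uncalled with the length and GC offset in libraries labelled knockout (-0.24 and -0.22). Atf4 was at 0.31 in control islets (adjusted p = 0.0422) and 0.44 in libraries labelled knockout (adjusted p = 0.0136). It missed the threshold in control islets without control azoramide library 1 (0.28) or 2 (0.29) or control DMSO library 1 (0.32) or 3 (0.17), and in the other genotype without labelled knockout DMSO library 1 (0.41) or 2 (0.48). With plain library totals Atf4 was at 0.14 and 0.29 and was called in neither. Ddit3 was at 0.49 and 0.69, and missed it without control azoramide library 1 (0.43), 2 (0.52) or 3 (0.53) and without labelled knockout DMSO library 1 (0.61); with the length and GC offset it was at 0.26 and 0.46 and was called in neither. With plain library totals it was at 0.32 in control islets and not called.

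ER calcium genes were mixed. The pump genes Atp2a3 and Atp2a2 fell by 0.81 and 0.43 in control islets and by 1.02 and 0.49 in libraries labelled knockout, and the IP3 receptor gene Itpr2 by 0.63 and 0.92, while the ER calcium leak channel gene Tmco1 rose by 0.63 and 0.71. Atp2a3 and Itpr2 were at -0.52 and -0.32 in control islets with the length and GC offset. Of 22 tested, 4 rose and 6 fell, and 3 rose and 9 fell, without a call for the list (adjusted p = 0.441 and 0.153), though fry called it downward in both (adjusted p = 0.0408 and 0.00357) and the medians turned to 0.11 and 0.05 with the length and GC offset.

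Ribosomal protein and respiratory chain genes rose nearly as whole lists. All 32 ribosomal protein genes rose in both genotypes, with medians of 0.82 and 0.80 (adjusted p = 9.0e-51 and 3.1e-36). Of 36 nuclear-encoded respiratory chain genes 33 and 32 rose and none fell (medians 0.66 and 0.70, adjusted p = 1.3e-28 and 2.8e-25), such as Cox6b1 (1.02 and 1.04) and Ndufa4 (1.06 and 1.15). With the length and GC offset the medians were 0.42 and 0.44, Cox6b1 was at 0.65 and 0.64 and Ndufa4 at 0.52 and 0.53. Of 13 mitochondrially encoded genes 12 rose in each (medians 0.75 and 0.80), including mt-Atp6 (0.82 and 0.86) and mt-Co2 (0.79 and 0.84), yet with the length and GC offset the medians were 0.05 and -0.02 with adjusted p = 0.838 and 0.689. With an estimated correlation the adjusted p for ribosomal protein genes was 0.102 and 0.253, for respiratory chain genes 0.175 and 0.253, and for mitochondrially encoded genes 0.276 and 0.380. Shares of counts differed accordingly: mitochondrially encoded genes held 7.90% of counts with azoramide and 5.34% with DMSO, ribosomal protein genes 3.01% and 1.92%, and Ins1 2.18% and 3.41% (exact permutation test over 6 and 5 libraries, p = 0.00217, adjusted p = 0.00433 each, with no overlap between treatments).

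The azoramide effect also followed transcript structure. Across 15084 genes with a length, Spearman's rho of the log2 fold change with exonic length was -0.34 in control islets and -0.29 in libraries labelled knockout, and with GC content -0.31 and -0.36. In each of the 6 azoramide libraries short transcripts stood above long ones relative to the mean of all libraries, by 0.14 to 0.38 on the log2 scale, and in each of the 5 DMSO libraries below them. With the length and GC offset, 27 of 60 called genes picked for the text moved by over 1.5 times in control islets, 26 of them to smaller values. In libraries labelled knockout 21 of 60 did, 20 of them to smaller values. Of each 60, 12 and 10 were no longer called. Among matched random lists, medians of ribosomal protein, respiratory chain and interferon-response genes lay at percentile 100 in both genotypes. Heat shock genes lay at 99.7 and 99.9, and lipogenic genes at 0.04 and 0.38. Mitochondrially encoded genes lay at 93.7 and 93.5, and autophagy and lysosome genes at 96.0 and 91.3. These percentiles compare genes with genes and do not measure the spread between libraries.

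**Figure D2:**
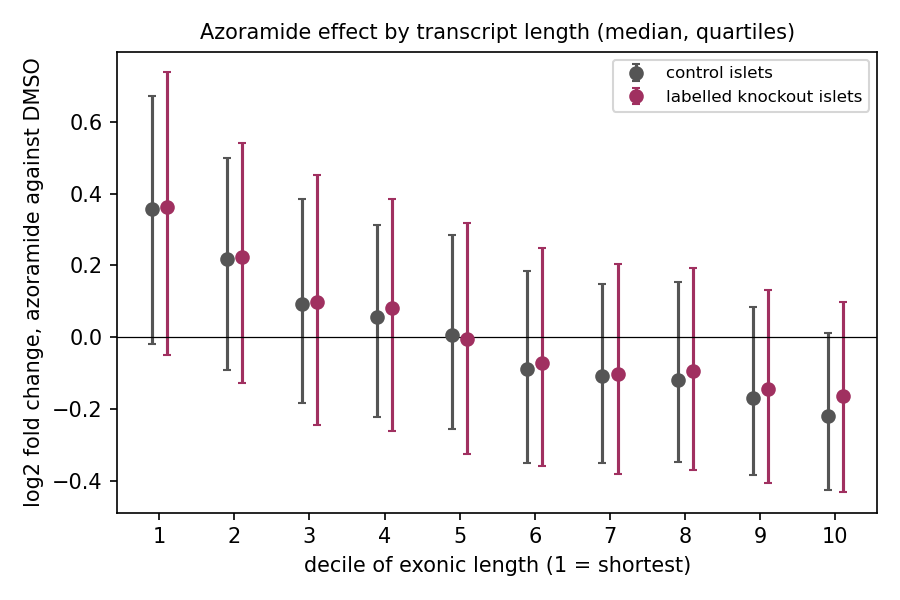
Log2 fold change, azoramide against DMSO (vertical axis), by decile of exonic length from shortest to longest (horizontal axis), in control islets and libraries labelled knockout; points are medians over genes and bars reach from the lower to the upper quartile. The medians decline from short to long transcripts, with Spearman's rho of -0.34 and -0.29 across genes.

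Of 20 lipogenic genes 10 fell and 1 rose in control islets (median -0.40, camera adjusted p = 0.00359) and 9 fell and 1 rose in libraries labelled knockout (median -0.40, adjusted p = 7.8e-04); with an estimated correlation the adjusted p was 0.280 and 0.380. With the length and GC offset the medians were -0.15 and -0.25, still called. Fatty acid synthase (Fasn) fell by 0.60 and 0.81, the desaturase gene Scd2 by 0.67 and 0.82 and the phosphatidate phosphatase gene Lpin1 by 0.98 and 1.02. The carbohydrate-responsive regulator gene Mlxipl was at -1.16 (edgeR adjusted p = 0.0192) and -1.57. With the length and GC offset Fasn was at -0.12 in control islets and not called, and at -0.26 in libraries labelled knockout. Cholesterol synthesis genes had medians of -0.25 and -0.30 (adjusted p = 0.258 and 0.0190). Beside matched random lists these lay at percentiles 0.04 and 0. With the length and GC offset the medians were -0.12 and -0.25, and with plain library totals -0.42 and -0.46, called in libraries labelled knockout only. The call in libraries labelled knockout ended with an estimated correlation (adjusted p = 0.631) and without labelled knockout azoramide library 3 (median -0.31, adjusted p = 0.0876). The control list was called without control DMSO library 2 (-0.24, adjusted p = 0.0317). Srebf2 and Insig1, regulators of that pathway, fell by 0.68 (0.25 with the offset) and 0.87 in libraries labelled knockout, while Msmo1, an enzyme of it, rose by 0.45 and 0.44 in control islets and libraries labelled knockout. Pdk4, a kinase that restrains pyruvate oxidation, rose by 1.01 and 1.26.

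Of 24 oxidative stress genes 11 rose and none fell in control islets (median 0.21, adjusted p = 6.6e-05; 0.276 with an estimated correlation), and 10 rose and 1 fell in libraries labelled knockout (median 0.41, adjusted p = 0.00254; 0.433 with an estimated correlation). The medians were 0.05 and 0.26 with plain library totals and 0.29 and 0.29 with the length and GC offset, still called in each, and 0.21 and 0.41 lay at percentiles 63.5 and 97.9 of matched random lists. Without control DMSO library 2 the control median was 0.34. Prdx1 rose by 0.82 and 0.80 and thioredoxin (Txn1) by 0.71 and 0.71, with 0.52 and 0.45 and 0.28 and 0.23 under the offset. Nqo1, a quinone reductase, rose by 0.87 in control islets (0.49 with the offset); its value in libraries labelled knockout was 0.52, and 0.33 (adjusted p = 0.0924) without labelled knockout DMSO library 2 or 0.11 (adjusted p = 0.573) with the length and GC offset. Of 16 cytosolic heat shock genes 6 and 8 rose, and 1 fell in libraries labelled knockout (adjusted p = 0.00849 and 0.00298; 0.438 and 0.433 with an estimated correlation; control median 0.40, or 0.24 with plain library totals), with Hspa8 at 0.78 and 0.72 and Hsp90aa1 at 0.58 and 0.63. Of 29 autophagy and lysosome genes 12 and 13 rose and 3 and 5 fell (adjusted p = 0.00849 and 0.0373; 0.371 and 0.485 with an estimated correlation), with Lamp2 at 0.69 and 0.80 and cathepsin B (Ctsb) at 0.87 in control islets. With plain library totals the control median of this list moved from 0.18 to 0.01, still called. The second call ended without labelled knockout azoramide library 1 (median 0.14) or 3 (0.17) or labelled knockout DMSO library 1 (0.12), and with plain library totals (median 0.02).

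Interferon-response genes rose in part. Of 30 tested, 10 rose and none fell in control islets (median 0.51, adjusted p = 0.00359), and 11 rose and 1 fell in libraries labelled knockout (median 0.59, adjusted p = 0.0171); with an estimated correlation the adjusted p was 0.754 and 0.708. Bst2 rose by 1.13 and 1.12, Usp18 by 0.81 in control islets and Isg15 by 1.38 in libraries labelled knockout, where B2m was at 1.18, or 1.03 (adjusted p = 0.0737) without labelled knockout DMSO library 2 and 0.40 (adjusted p = 0.158) with the length and GC offset. The second list call ended without labelled knockout azoramide library 2 (median 0.27) or DMSO library 2 (0.39). The list of NF-kB genes had 5 that rose in each genotype and none that fell, with adjusted p = 0.441 and 0.0475 (0.689 with an estimated correlation). The control list was called without both libraries that stood apart (median 0.64, adjusted p = 0.0241). The second call ended without labelled knockout azoramide library 1 (median 0.61) or 2 (0.48) or DMSO library 2 (0.49). Interleukin 1 beta (Il1b) was at 0.94 in control islets, with 0.86 and 0.65 and no call without control azoramide library 3 or control DMSO library 3 and 0.60 (adjusted p = 0.120) with the length and GC offset, and at 1.41 in libraries labelled knockout, with 1.25 and adjusted p = 0.0512 without labelled knockout DMSO library 1.

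Markers of other islet cells differed with treatment as well. Mean log2 CPM was higher with azoramide by 0.31 for alpha cell markers and by 0.47 for delta and PP cell markers, and for endothelial markers the difference was -0.20 (exact permutation test, adjusted p = 0.0216, 0.0216 and 0.0216 over 10 lists; 0.0758 for alpha cell markers with plain library totals, where the difference was 0.15), such as Ptprb (-0.72 and -0.66; -0.46 and -0.41 with the offset). Camera at the preset correlation did not call endothelial markers (adjusted p = 0.0699 and 0.0540), while fry did (0.0364 and 0.0238). Camera calls ended with the length and GC offset for delta and PP cell markers in both genotypes (medians 0.50 to 0.33 and 0.36 to 0.22, adjusted p = 0.112 and 0.130). That for alpha cell markers ended in libraries labelled knockout (0.42 to 0.19, adjusted p = 0.106). The delta and PP call also ended in control islets without control azoramide library 2 (0.45, adjusted p = 0.0514). In libraries labelled knockout it ended without azoramide library 3 (0.26, adjusted p = 0.0557), and without DMSO library 1 the median was 0.25. None of these camera calls held with an estimated correlation (smallest adjusted p = 0.280). Acinar markers ranged from 3.47 to 6.97 between libraries with no call by treatment (adjusted p = 0.254). By genotype over both treatments this test called no marker list (smallest adjusted p = 0.974). It redrew genotype without regard to treatment, so differences between treatments could hide smaller ones between genotypes. Camera at the preset correlation called, besides acinar and macrophage markers, hepatocyte markers with DMSO (-0.30, adjusted p = 0.00659) and erythroid markers with DMSO (0.67, adjusted p = 0.00488) and azoramide (-0.76, adjusted p = 3.3e-04). Without control DMSO library 2 both calls with DMSO ended, at -0.14 (adjusted p = 0.184) for hepatocyte and 0.57 (adjusted p = 0.0709) for erythroid markers. Without labelled knockout DMSO library 2, which leaves 1 library in that group, the medians were -0.34 and -0.17. No marker list was called with an estimated correlation (smallest adjusted p = 0.636). Macrophage markers had 2 that rose and 2 that fell in control islets and 7 that rose in libraries labelled knockout (adjusted p = 0.816 and 0.114; 0.00186 without labelled knockout azoramide library 3 in the second, median 0.94), with Cd68 at 1.04 and 1.46. Kit fell by 1.40 in control islets. Of 24 apoptosis genes 6 rose and 4 fell, and 6 rose and 6 fell, with Bbc3 at -0.63 and -0.84, not called in control islets with the length and GC offset (-0.34).

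**Figure D3:**
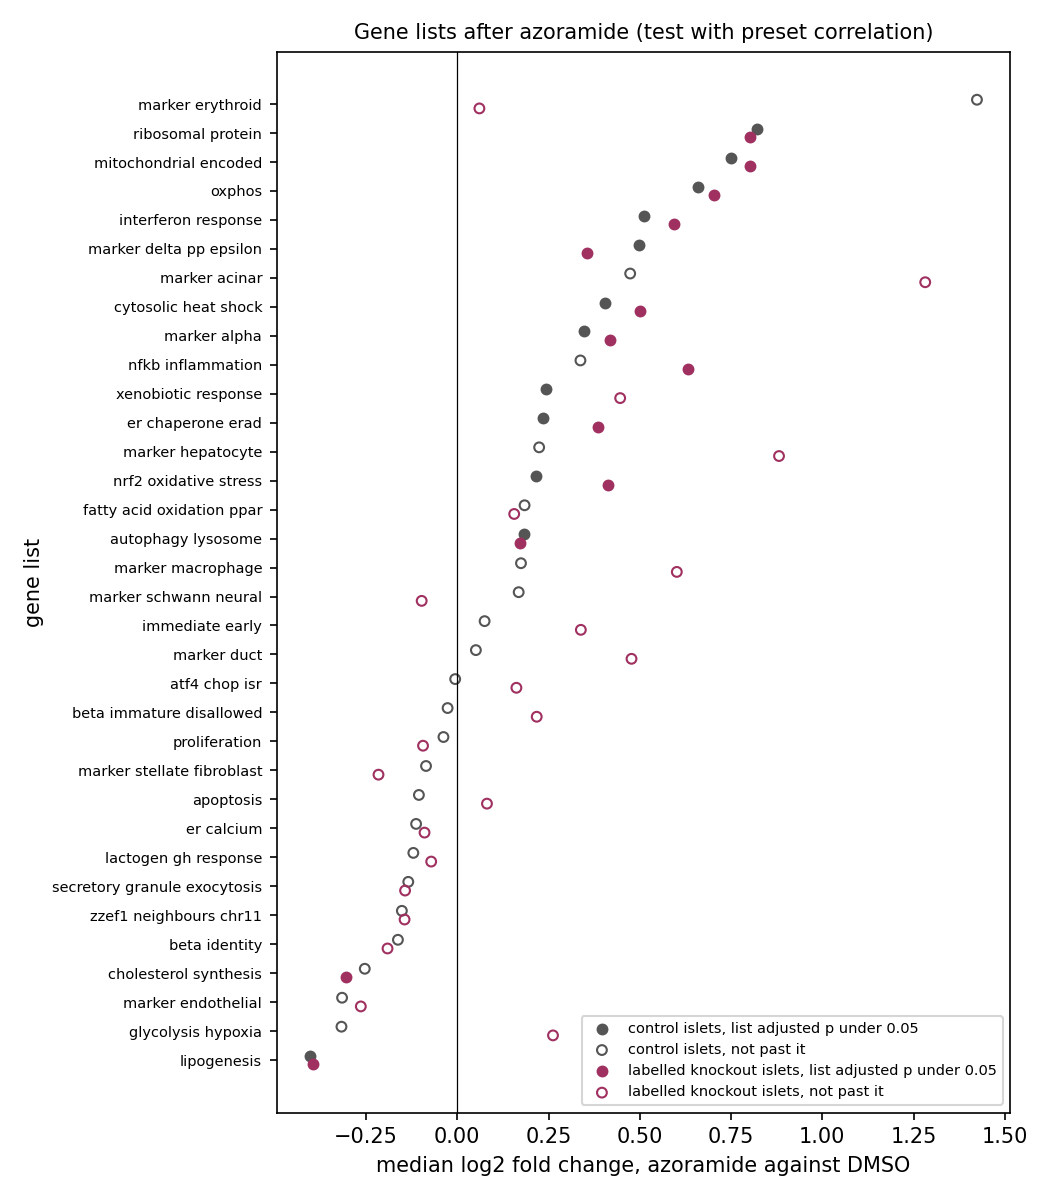
Median log2 fold change, azoramide against DMSO (horizontal axis), of each of the 34 gene lists (vertical axis) in control islets and libraries labelled knockout; filled points are lists with an adjusted p under 0.05 at the preset correlation. Ribosomal protein genes had medians of 0.82 and 0.80, and lipogenic genes -0.40 in both.

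Whether genotype altered the response to azoramide was asked last. Effects in control islets and in libraries labelled knockout correlated across genes with Pearson's r = 0.60 and Spearman's rho = 0.75, with the same sign for 83.2% of genes, against 50.0% in simulated groups without effect; these comparisons share no library. Past the threshold in both were 2389 rising and 2344 falling genes, where independent lists would share 581 and 592, and 0 genes were called in opposite directions. The trend with transcript length, seen in both genotypes, could add to this agreement. No gene passed the edgeR test of the interaction (563 at an unadjusted p under 0.05; DESeq2 called 0, and 1 gene passed without control DMSO library 2, 1 without labelled knockout azoramide library 3 and 6 without both). Interaction values were 0.17 for Hspa5 (SE 0.19), -0.21 for Atp2a3 (SE 0.13), -0.05 for Ins1 (SE 0.13) and 0.39 for Zzef1 (SE 0.12, adjusted p = 0.999). Zzef1 itself fell with azoramide by 0.55 in control islets (adjusted p = 3.5e-05; -0.22 and adjusted p = 0.0673 with the length and GC offset) and was at -0.16 in libraries labelled knockout (adjusted p = 0.153). There it was 0.16 with the length and GC offset (adjusted p = 0.237), and was called with plain library totals (-0.32, adjusted p = 0.00649) and with acinar markers as a covariate (-0.23, adjusted p = 0.0469). Among established symbols the 5 of smallest p were Sowahb (-0.95), Taf9 (0.93), Zfp160 (0.48), Dpy19l4 (0.40) and Foxn1 (-4.92, below 1 CPM in every group). Of 34 lists 9 passed with the preset correlation and none with an estimated one, with adjusted p = 0.849, or with fry.

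It was also asked whether the genotype effect with DMSO pointed along or against the azoramide effect. Its correlation across genes with the azoramide effect in libraries labelled knockout, which shares the labelled knockout DMSO libraries, was -0.50, where simulated unchanged groups gave -0.61; the covariance was -0.10 against a simulated -0.06. With the azoramide effect in control islets, which shares the control DMSO libraries, it was 0.17 against a simulated 0.44, with covariances of 0.03 and 0.04, and among 9932 genes with log2 CPM of at least 3 it was -0.27 against a simulated 0.45 (0.36 to 0.49), with covariances of -0.0148 and 0.00823. In the same 9932 genes the correlation with the azoramide effect in libraries labelled knockout was -0.57 against a simulated -0.60. The covariance there was -0.0358 against a simulated -0.0123 (-0.0139 to -0.01135). The simulated groups hold no azoramide effect, whereas the measured ones differ widely by treatment, so measured and simulated correlations are not directly comparable. Simulated genes also vary independently, so trends shared by many genes of a library are not part of these ranges. The shared groups of 2 and 3 libraries could not be split into parts of 2, and part of each value comes from the shared libraries.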

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

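The lists themselves were fixed before the data were examined, while leaving out each library and the joint removal of libraries were added to the list tests after the results were seen. For 9 lists the azoramide effect in libraries labelled knockout minus that in control islets passed with the preset correlation. None of the 9 passed with an estimated correlation, where each had adjusted p = 0.849, or with fry, where the smallest adjusted p = 0.824, and none of their members passed alone. The median difference was 0.124 for ER folding and degradation genes (adjusted p = 0.00596), 0.146 for integrated stress response genes (0.0132), -0.102 for cholesterol synthesis genes (0.00344), 0.398 for NF-kB genes (0.00344) and 0.394 for immediate early genes (0.0222). It was 0.827 for acinar markers (0.00628), 0.489 for macrophage markers (8.9e-04), 0.567 for glycolysis and hypoxia genes (4.6e-11) and -1.46 for the 5 erythroid markers (3.2e-06).

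The calls for glycolysis and hypoxia genes and erythroid markers were kept in all 11 fits that left out 1 library, though the first median was 0.189 without control DMSO library 1 and the second -0.419 (adjusted p = 0.0429) without labelled knockout DMSO library 2. Macrophage markers were at 0.0403 (adjusted p = 0.377) without labelled knockout azoramide library 1. Without control DMSO library 2 the medians were 0.0366 for ER folding genes, -0.0170 for integrated stress response genes, -0.0701 for cholesterol synthesis genes, 0.135 for NF-kB genes, 0.0538 for immediate early genes and -0.367 for acinar markers, all past the threshold no longer. Further libraries ended single calls: for ER folding genes control azoramide library 1 (0.0918) and labelled knockout azoramide library 1 (0.0929), and for NF-kB genes labelled knockout azoramide library 2 (0.181) and DMSO library 2 (0.263). For integrated stress response genes these were control azoramide library 3 (0.105), labelled knockout DMSO library 1 (0.0820) and azoramide library 3 (0.0732). For cholesterol synthesis genes they were control azoramide library 2 (-0.0457), labelled knockout DMSO library 1 (-0.113) and azoramide library 3 (-0.0635). Immediate early genes lost the call without control azoramide library 1 (0.325) or 3 (0.328), labelled knockout DMSO library 1 (0.358) or azoramide library 2 (0.278), and acinar markers without control azoramide library 1 (0.515), labelled knockout azoramide library 2 (0.0857) or DMSO library 2 (0.158).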

How the results depend on the processing

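Plain library totals, the length and GC offset, the joint removal of labelled knockout azoramide library 3 and control DMSO library 2, the average over treatments and the list tests on fewer libraries were chosen after the data were seen. Genes called for genotype with DMSO numbered 0, against 2 without a filter, 1 with the replicate number as a block, 2 without both libraries, 3 with DESeq2 and 0 to 3 with 1 library left out. With azoramide the numbers were 0, 84 without both libraries, 2 with DESeq2 and 0 to 3 with 1 library left out. For the average they were 0, 1 with the block, 10 without both libraries, 1 with DESeq2 and 0 to 1 with 1 library left out. For the interaction they were 0, 6 without both libraries, 1 with the replicate block of genotype by number and 0 to 1 with 1 library left out. For azoramide in control islets they were 5893, 3490 with the offset, 266 at 2-fold and 4820 to 6016 with 1 library left out. In libraries labelled knockout they were 6006, 3721 with the offset, 469 at 2-fold and 4015 to 6202 with 1 library left out. Where 1 labelled knockout DMSO library remained, it was assumed to vary like the other groups. The cause was not tested, except that a minimum change removes calls by construction.

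Lists called for genotype with DMSO numbered 12, against 6 without both libraries, 0 with an estimated correlation, 0 with fry and 6 to 15 with 1 library left out. With azoramide they numbered 7, 0, 0 and 6 to 11 in the last 3 of these settings. For azoramide they numbered 12 in control islets and 13 in libraries labelled knockout, against 0 and 0 with an estimated correlation, 18 and 19 with fry and 11 to 15 and 11 to 13 with 1 library left out. For the interaction they numbered 9, against 3 without both libraries, 0 with an estimated correlation, 0 with fry and 4 to 11 with 1 library left out.

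Among genes with log2 CPM of at least 3 the azoramide effects in both genotypes correlated at 0.90. The genotype effect with DMSO correlated with the azoramide effect in libraries labelled knockout at -0.57 there and at -0.56 with the replicate block. With that in control islets it stood at -0.27 (simulated 0.45), turned from 0.17, and at 0.11 with the block. Per plain total Zzef1 was at 62.3 CPM in control azoramide libraries and 87.6 CPM in labelled knockout DMSO libraries. For pairing, the deviations of each library from its group mean per gene were correlated between the treatments of a genotype. Libraries with the same number gave -0.144 to 0.107, 1 of 5 pairs over 0.1, and those with other numbers -0.155 to 0.155. In the group of 2 the deviations mirror each other, so each value there recurs with the opposite sign. The number was therefore not taken to pair them. With 2 or 3 libraries per group this check is weak and cannot exclude shared islets. The column names carry the same number in both treatments, which leaves pairing possible. With genotype by number as a block, azoramide gave 6004 called genes in control islets and 6162 in libraries labelled knockout.

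Of the 140 genes past the threshold that the naming rule gave for control islets, 25 lost the call without some library and 39 with the offset; of the 60 picked for the text, nearly all of them printed there, 6 did without some library. In libraries labelled knockout these were 34 and 36 of 142, and 9 of 60. Of the rule's genes left out of the text 19 and 25 were lost, so the text, whose genes were picked after their values were seen, holds the steadier part of the rule's genes. No called gene picked for the text turned direction.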

Other observations

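The tests of transcript length and GC content and of nuclear RNAs, and the splits of the control libraries, were set before their results were seen; the tests of scaling, of Zzef1, of genotype labels, of aryl hydrocarbon receptor targets and the other splits were chosen after. Lists that camera at the preset correlation, with all libraries, called in neither genotype included fatty acid oxidation genes (22 tested, 7 and 8 rose and 2 and 2 fell with azoramide, adjusted p = 0.201 and 0.183). Others were glycolysis and hypoxia genes (25 tested, 2 and 5 rose and 7 and 2 fell, 0.143 and 0.264) and proliferation genes (21 tested, 0 and 0 rose and 1 and 0 fell, 0.751 and 0.995). Genes of lactogen response had 2 and 3 that rose and 4 and 4 that fell of 20 (0.751 and 0.928), immediate early genes 1 and 3 that rose and 0 and 2 that fell of 23 (0.712 and 0.154), and genes beside Zzef1 on chromosome 11 had 2 and 2 that rose and 4 and 4 that fell of 16 (0.543 and 0.264). Genes of immature or disallowed beta cell expression had 4 and 4 that rose and 2 and 0 that fell of 22 (0.684 and 0.268). Fry called fatty acid oxidation genes upward (adjusted p = 0.00981 and 0.0140) and genes beside Zzef1 downward (0.0229 and 0.0013) in both genotypes. Camera called glycolysis and hypoxia genes downward in control islets without control DMSO library 2 (-0.40, 0.0373) or 3 (-0.48, 0.00589). Both fits kept control DMSO library 1, where this list was at 6.39 mean log2 CPM, against 5.53 to 5.73 in the other control libraries of both treatments. These calls therefore lean on that 1 library. With the length and GC offset it called immediate early genes upward in libraries labelled knockout (0.47, 0.0199). Xenobiotic response genes, with 2 and 5 of 10 that rose and 1 and 1 that fell, were called in control islets (0.0463 and 0.125; 0.276 and 0.433 with an estimated correlation), a call that ended without control azoramide library 2 (median 0.26), control DMSO library 2 (0.22) or control DMSO library 3 (0.20) and with the length and GC offset (0.12, adjusted p = 0.102); with plain library totals the median was 0.07.

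Duct markers had 5 and 4 that rose and 2 and 2 that fell of 15 (adjusted p = 0.420 and 0.268), stellate and fibroblast markers 1 and 0 that rose and 4 and 3 that fell of 20 (0.441 and 0.270), and Schwann and neural markers 0 and 0 that rose and 1 and 1 that fell of 9 (0.816 and 0.511). Hepatocyte markers had 2 and 3 that rose of 8 (0.258 and 0.107), and erythroid markers 4 and 0 that rose of 5 (0.0699 and 0.928). Acinar markers had 0 and 0 that rose and 1 and 1 that fell of 31 (0.445 and 0.0734), with upward calls in other settings, such as without control DMSO library 2 (median 1.67, adjusted p = 0.00434) and without labelled knockout DMSO library 1 (2.63, adjusted p = 3.9e-04).

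Ribosomal protein genes rose in both genotypes, a pattern that differences in RNA quality or scaling could also give. With the length and GC offset the median in control islets was 0.624 (0.588 to 0.702), and with plain library totals 0.654 (0.626 to 0.696). On these medians neither the trend nor the scaling accounts for the whole rise. The ranges in brackets in this paragraph come from drawing the genes of a list again 2000 times. They show the spread between genes, not between libraries, and genes of a list are not replicates. A lower share of nuclear transcripts in the azoramide libraries stays open: the median of 16 nuclear-retained RNAs was -0.0740 (-0.283 to 0.0576) in control islets, with 7 that fell and none that rose, an interval too wide to decide. In libraries labelled knockout their median was 0.0132, with 3 that rose and 2 that fell, beside a median of 0.80 for ribosomal protein genes. A response of islet cells to azoramide is also open.

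Zzef1 in libraries labelled knockout was not lower by as much as loss of the whole transcript from most islet cells would give, with a log2 fold change of -0.255 with DMSO (-0.439 to -0.0716). Deletion of a short exon may go unseen if the rest of the transcript keeps its level, which was not tested. On that assumption, loss of an exon of median length would change the count per gene by -0.0191 on the log2 scale. Loss of the longest exon in all cells would then change the count by -0.358. That value lies inside the interval with DMSO but outside that of the average over treatments, which was -0.0627 (-0.186 to 0.0607). The average joins a lower value with DMSO and a higher one with azoramide. The deleted exons are not given in the sources used here. Swapped labels cannot be told apart either, since the genotype effects with DMSO and with azoramide correlated at -0.0358 across genes, inside the -0.0603 to 0.0288 of unchanged simulated groups. Among genes with log2 CPM of at least 3 the value was -0.0767, just outside -0.0606 to 0.0595, a range from genes drawn independently that leaves the question open.

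The rise of Cyp1a1 may reflect activation of the aryl hydrocarbon receptor. Of 3 other targets tested, 1 passed upward in control islets, Nqo1 (0.87), with Tiparp at 0.10 and Ugt1a6a at -0.35, and 2 in libraries labelled knockout, Nqo1 (0.52, lost without labelled knockout DMSO library 2 at 0.33) and Tiparp (0.46). The bound set against such activation, at most 1 of these targets past the threshold upward in control islets, was met there. Nqo1 is also a member of the list of oxidative stress genes, which was called upward with azoramide in both genotypes. Its call in libraries labelled knockout also ended with the length and GC offset. With 2 of the 3 passing in libraries labelled knockout, so few targets do not decide the question.

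Of the 10 splits of the 6 control libraries, 1 gave as many genes as the real one, which is the real one itself (5893 genes; highest other 0), and 10 splits are too few for a share under 0.05. For genotype with azoramide the real split called 0 genes in edgeR (754 at an unadjusted p under 0.05; DESeq2 called 2). No split can call fewer, so that all 10 gave at least as many tests nothing; the highest other called 3. For genotype averaged over treatments, where edgeR called 0 genes (726 at an unadjusted p under 0.05; DESeq2 called 1), the same holds for the 100 splits drawn of 200 possible. Of these, 13 called any gene, 7 of them a single one, and the highest called 49 and 90; whether the samples hold a structure behind those was not tested.

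The 84 genes called for genotype with azoramide once both libraries that stood apart were left out were examined after their values were seen. They included Rgs2 (0.67), Serping1 (0.53), Ctsc (1.07) and Chgb (0.54), and the macrophage genes Csf1r (1.06), Tyrobp (1.35) and Fcgr3 (1.54). Rgs2, Serping1 and Ctsc stood at the same values (0.67, 0.53 and 1.07) when only labelled knockout azoramide library 3 was left out. Control DMSO library 2 is in neither group of this comparison. Macrophage markers averaged 3.17 and 2.78 log2 CPM in labelled knockout azoramide libraries 1 and 2, which were kept. They were at 2.07 in the removed library 3 and at 1.93 to 2.52 in control azoramide libraries. Acinar markers were at 4.32 in the removed library 3, against 5.98 and 6.97 in libraries 1 and 2. In control DMSO library 2 they were at 6.77, against 4.57 and 4.20 in control DMSO libraries 1 and 3. Cell content was not tested as a cause. Both libraries were left out because of their place on the principal components, which is itself a measured outcome, and none of these genes passed in edgeR with all 11 libraries.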
